A study of Rattus norvegicus with 12 samples.

How the data were processed

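A piece of lung from each of 12 male F344 rats, 3 months of age when bought, was sequenced, with 6 rats exposed to air and 6 to CNC. Per the labels' protocols, total RNA was isolated with a column kit that retains small RNA, and strand-specific libraries of polyadenylated RNA were amplified over 12 PCR cycles. The rats were housed 3 per cage, and which rats shared a cage was not analysed here. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic 0.35, HISAT2 2.1.0, Cufflinks, SAMtools 1.8 and HTSeq 0.11.2, without roles. The authors deposited a single table of raw counts per gene symbol, whole numbers for 30045 symbols in 12 libraries, with no normalization. The rat build Rnor6 appears in the name of the deposited count table, and the annotation and the strand setting of the counting are not given in the sources used here. Antisense and overlapping genes and near-identical copies are therefore uncertain: 549 symbols carry a copy suffix, of which 93 were tested and 13 changed.

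Groups were taken from the treatment named in the labels, and replicate numbers only name a rat. Library totals ran from 8693259 to 16603697 counts, and amplified reads are not independent molecules. No 2 libraries looked like a repeat of each other: over the 30 pairs within a group the chi-square of the counts per degree of freedom ran from 2.62 to 8.31, where sampling noise alone gives 1. Gene symbols were matched to a RefSeq gene table of another assembly (GRCr8) for names alone, where 19073 symbols matched directly and 2409 more through a synonym. No gene positions are given, since no annotation of the build of the counts was used here.

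Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), leaving 15019, scaled by TMM and tested with glmQLFit and glmQLFTest (robust = FALSE), CNC against air, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are TMM-scaled, log2 CPM use a prior count of 2, and the common biological coefficient of variation was 8.05%. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry, and with a 2-sided exact permutation test over all 924 splits of the 12 rats into 6 and 6 of each list's mean per rat. The procedure was tested on simulated data of 14927 genes, where 46.0, 70.0, 90.0 and 100.0% of genes changed by 1.25-, 1.5-, 2- and 4-fold were recovered, and 9 of 162 calls were unchanged genes. Only 50 genes were changed at each fold, and genes varied independently. In the real data 24.6% of tested genes changed, so the recovery there may differ.

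The test design, the 49 gene lists, the rule for named genes and the other settings to try were chosen before the data were examined. The rule names the 12 largest rises and the 12 largest falls among changed genes with a mean of at least 1 CPM and a proper symbol. It adds up to 4 called members of smallest adjusted p from each list, and a panel of genes named whatever their result (Ccl2, Cxcl1, Il1b, Tnf, Il6, Lcn2, Spp1, Gpnmb, Mmp12, Chi3l1, Lgals3, S100a8, S100a9, Hmox1, Nqo1, Muc5ac, Sftpc, Scgb1a1, Slc26a4, Mki67, Col1a1 and Timp1). The other clauses, for lists called without called members and for fewer than 10 passing genes, did not apply. Some single genes that the rule or a small count would name are not reported here. Alternatives were other scalings (DESeq2 1.42.0 size factors, upper quartile, library size alone), other filters, the DESeq2 Wald test, limma-voom (limma 3.58.1) with and without quality weights, robust edgeR, 1 surrogate variable (sva 3.50.0), other thresholds and leaving out each rat. A clock gene covariate, a heart muscle covariate and fits without air replicates 4 and 5 and without CNC replicates 3 and 6 were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.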

Results

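Gene expression was measured by RNA sequencing in a piece of lung from each of 12 male rats of the inbred strain F344. The rats inhaled either air or crystalline nanocellulose (CNC), rod-like crystals obtained from plant cellulose, with 6 rats in each group. CNC was given in whole-body chambers at 20 mg/m3 for 6 hours a day, 5 days a week, over 14 days of exposure, and lungs were taken 1 day after the last. The air libraries held 13788908, 16603697, 12063272, 12862907, 10281138 and 8693259 counts over genes, and the CNC libraries held 12423908, 12901119, 14138322, 14735245, 12680562 and 9917387. Library size did not separate the groups (2-sided exact permutation test, p = 0.745). The design asks which genes of the lung respond to repeated CNC inhalation.

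After CNC, most genes of the complement and acute phase list and of the phagocyte activation list rose. Most endothelial genes (26 of 30 tested) and red cell genes (7 of 9 tested) fell. Both lists were called by camera (adjusted p = 1.35e-16 and 4.34e-06), by fry and by the exact permutation test. Both camera calls were lost with an estimated correlation (adjusted p = 0.0625 for each). Lcn2, an iron-sequestering acute phase protein, rose from 13.4 ± 5.78 to 71.4 ± 10.3 CPM (SD, n = 6 per group), or 5.49-fold (log2 fold change 2.46 ± 0.20 SE). Slc26a4, an epithelial anion exchanger, rose 9.8-fold, from 6.97 ± 3.85 to 66.5 ± 10.9 CPM. Eln, which encodes elastin, fell 2.06-fold, from 596 ± 69.2 to 289.9 ± 45.5 CPM, and Dlk1, an imprinted gene of the Notch ligand family, fell 20.9-fold, from 9.97 ± 5.58 to 0.464 ± 0.207 CPM. For each of these 4 genes all 6 CNC rats lay outside the range of the air rats.

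By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3691 of 15019 tested genes changed (24.6%), of which 1981 were higher and 1710 lower in CNC. The split depended on scaling: with library size alone, 1683 were higher and 2151 lower. Most changes were small, since 542 genes changed by at least 1.5-fold (426 higher and 116 lower) and 165 by at least 2-fold (142 higher and 23 lower). In 1730 genes (11.5%) the groups did not overlap, against 0.216% expected by chance, and 1711 of these were among the changed genes. The first principal component of the 2000 most variable genes held 30.6% of the variance and separated the groups (exact permutation test, adjusted p = 0.00866), and the second held 17.5% and did not (exact permutation test, adjusted p = 0.961). With a covariate built from circadian clock genes, which differed between the groups, 922 genes passed, and of 184 genes followed singly 94 kept their result, 88 lost their call and 2 turned in direction. Over the 3691 changed genes the fold with it was a median of 0.955 of that without it, 96.7% kept their sign, and the standard error rose by a median factor of 2.01.

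**Figure D1:**
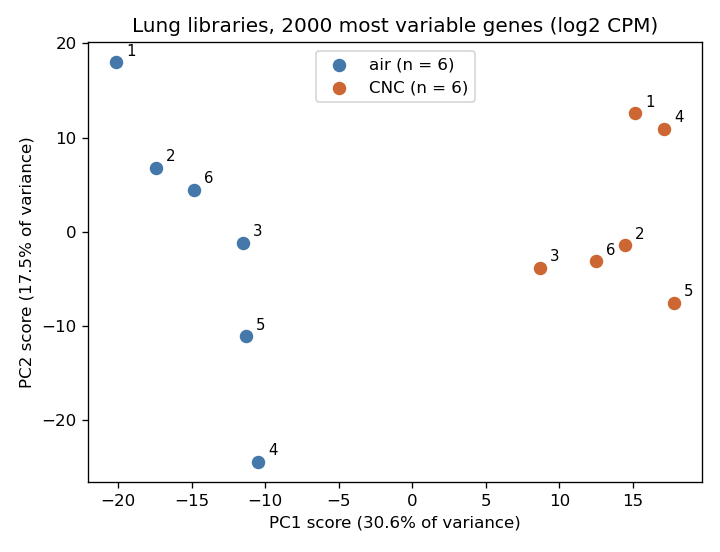
Scores of the 12 lung libraries on the first and second principal components of log2 CPM of the 2000 most variable genes, 1 point per rat, numbered by replicate within the air (blue) and CNC (orange) groups. The groups lie apart on PC1, which holds 30.6% of the variance, and overlap on PC2, which holds 17.5%.

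Of 49 gene lists fixed in advance, 46 had enough tested members, and camera with a preset correlation of 0.01 called 28, of which 20 were higher and 8 lower in CNC. With a correlation estimated from the data 9 of the 28 passed. Other groupings of the same libraries also gave many lists by camera: 8 of 100 splits, the real one included, gave at least 28, and the highest of the others gave 33. The exact permutation test of each list's mean per rat, which had been fixed in advance as well, called 30 lists, 26 of them among the 28, and the highest of the other splits gave 8 by that test. The rotation test fry also called 30, 27 of them among the 28. The permutation test called 4 lists that camera did not, all with a higher mean in CNC. Of these, the circadian clock (permutation adjusted p = 0.00905, fry adjusted p = 0.000384) and inflammasome (permutation adjusted p = 0.0119, fry adjusted p = 0.00711) lists were called by fry too. The epithelial damage (permutation adjusted p = 0.00553, fry adjusted p = 0.124) and glucocorticoid (permutation adjusted p = 0.0275, fry adjusted p = 0.0898) lists were not. Fry alone called the endothelial adhesion list, as lower (adjusted p = 0.0495). The alveolar macrophage list was called by camera and by fry (adjusted p = 0.00281), and the heart muscle list by camera alone. The smallest p the permutation test can give is 0.00216. Below, a camera p is adjusted over the lists and the permutation p is not. With the clock covariate, lists were tested by camera at the preset correlation alone.

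Most acute phase and complement genes rose. In the complement and acute phase list 22 of 27 tested members rose and 1 fell (22 and 2 adjusted over the list alone), with a median log2 fold change of 0.47. The complement and acute phase list had camera adjusted p = 2.64e-23, exact permutation p = 0.00216 and adjusted p = 0.0214 with an estimated correlation. C3, the central complement protein, rose from 540.0 ± 75.9 to 1867 ± 241 CPM (SD, n = 6 per group), a 3.46-fold change (adjusted p = 2.84e-08 by edgeR). The alternative pathway factor Cfb rose 1.98-fold, the pattern-recognition protein Ptx3 2.63-fold and haptoglobin, Hp, 2.64-fold. Serpina1, an antiprotease, was the member that fell. Orm1, another acute phase protein, had the largest rise of all named genes, 18.2-fold, at a low level (from 0.12 ± 0.053 to 2.36 ± 0.751 CPM). Defb5 (14.9-fold), Itih1 (6.4-fold) and Saal1 (5.89-fold) were also among the 12 largest rises, as were Ly6al (7.06-fold) and Mab21l3 (6.25-fold).

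Most genes of the phagocyte activation and lipid handling list rose. In that list 17 of 21 tested members rose and 1 fell (18 and 2 adjusted over the list alone), with a median log2 fold change of 0.69. The phagocyte list had camera adjusted p = 1.87e-23, exact permutation p = 0.00216 and adjusted p = 0.0311 with an estimated correlation. The member that fell was the fatty acid binding protein Fabp4, and the Fabp4 call was lost without air replicates 1, 4 and 6 or CNC replicates 1, 3, 5 and 6 in turn (adjusted p from 0.0519 to 0.0745). The Fabp4 call also ended with each of the clock covariate, air replicates 4 and 5 left out and CNC replicates 3 and 6 left out (adjusted p from 0.0719 to 0.125). The chitinase-like protein Chi3l1 rose from 167 ± 27.3 to 599 ± 69.7 CPM (SD, n = 6 per group), or 3.59-fold, and the galectin Lgals3 rose 2.36-fold. Fabp5 rose 2.17-fold, the macrophage elastase Mmp12 4.86-fold, the matrix protein Spp1 2.81-fold and the transmembrane glycoprotein Gpnmb 2.07-fold. The Spp1 call ended with the clock covariate (log2 fold change from 1.49 to 0.96, adjusted p = 0.384). Among lysosome genes 27 of 34 tested members rose and 1 fell (29 and 1 adjusted over the list alone), with a median of 0.27. The lysosome list had camera adjusted p = 1.15e-22 and adjusted p = 0.0311 with an estimated correlation. Its called members included the proton pump subunit Atp6v0d2 (4.23-fold), the cathepsin Ctsz (1.83-fold), Cd68 (2.03-fold) and Cd63 (1.39-fold), while the cathepsin Ctsl fell. For cholesterol efflux and lipid storage 10 of 19 tested members rose and 1 fell (11 and 1 adjusted over the list alone). The cholesterol efflux list had camera adjusted p = 1.93e-05 and adjusted p = 0.0424 with an estimated correlation. Among its called members were Lipa (1.42-fold), Soat1 (1.37-fold) and Npc2 (1.51-fold), and Pltp fell.

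Most chemokine genes and neutrophil markers rose. Of the chemokines 16 of 26 tested members rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 0.57. The chemokine list had camera adjusted p = 4.3e-09, exact permutation p = 0.00216 and adjusted p = 0.0311 with an estimated correlation. The neutrophil attractant Cxcl6 rose 5.86-fold, Ccl22 5.09-fold, Ccl2 2.8-fold, Ccl3 2.07-fold and Cxcl1 2.02-fold, while Ccl21, Ccl24 and Cxcl14 fell. The Ccl21 call was lost without air replicates 3, 4, 5 and 6 or CNC replicates 1, 2, 3, 4 and 6 in turn (adjusted p from 0.0568 to 0.105). The Ccl21 call also ended with each of no count filter, limma-voom, limma-voom with quality weights, robust edgeR, the heart muscle covariate, the clock covariate, air replicates 4 and 5 left out and CNC replicates 3 and 6 left out (adjusted p from 0.0514 to 0.269). Among neutrophil markers 10 of 16 tested members rose and 1 fell (10 and 1 adjusted over the list alone). The neutrophil list had camera adjusted p = 3.55e-08, exact permutation p = 0.00216 and adjusted p = 0.0625 with an estimated correlation. The alarmin S100a9 rose from 73.2 ± 12.9 to 275 ± 68.8 CPM (SD, n = 6 per group), S100a8 rose 1.8-fold, Cd177 7.12-fold, the decoy receptor Il1r2 3.85-fold and Cxcr1 1.74-fold, while Ngp fell. In the cytokine list 9 of 17 tested members rose and 3 fell (9 and 4 adjusted over the list alone). The cytokine list had camera adjusted p = 0.0156 and adjusted p = 0.114 with an estimated correlation. There were rises of Csf1 (1.38-fold), Il1rn (1.58-fold), Il1a (1.51-fold) and Il1b (1.37-fold) and falls of the alarmin Il33 (1.23-fold), Il15 and Il34. The call of the cytokine list was also lost with the clock covariate (adjusted p = 0.21). Tnf and Il6 were below the count filter, with 25 and 10 counts summed over the air libraries and 70 and 16 over the CNC libraries. Tested without the filter, Tnf had adjusted p = 0.0551 by edgeR and 0.0351 by the DESeq2 Wald test.

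For monocyte and interstitial macrophage markers 10 of 18 tested members rose and 3 fell (10 and 3 adjusted over the list alone). The monocyte list had camera adjusted p = 5.71e-05, exact permutation p = 0.0173 and adjusted p = 0.253 with an estimated correlation. Lyz2, a macrophage and type 2 cell lysozyme, took 2.49 ± 0.211% of counts in CNC and 1.57 ± 0.162% in air (SD, n = 6 per group), and Itgam (1.71-fold) and Cd14 (1.32-fold) rose, while Csf1r, Lyve1 and Plac8 fell. In the alveolar macrophage list 8 of 16 tested members rose and 1 fell (8 and 2 adjusted over the list alone). The alveolar macrophage list had camera adjusted p = 4.87e-05 and adjusted p = 0.23 with an estimated correlation, with an exact permutation p of 0.0563 for its mean, and Plet1 (1.95-fold), Itgax (1.66-fold) and the scavenger receptor Msr1 (1.63-fold) rose, while Fabp4 fell, a call lost without air replicates 1, 4 and 6 or CNC replicates 1, 3, 5 and 6 in turn (adjusted p from 0.0519 to 0.0745). Among pattern recognition genes 18 of 30 tested members rose and 0 fell (19 and 0 adjusted over the list alone). The pattern recognition list had camera adjusted p = 9.8e-07 and adjusted p = 0.148 with an estimated correlation. Its called members included Card9 (1.64-fold) and Clec5a (1.62-fold). For MHC class II and dendritic cell genes 12 of 25 tested members rose and 1 fell (13 and 1 adjusted over the list alone). The MHC class II list had camera adjusted p = 3.7e-08 and adjusted p = 0.0765 with an estimated correlation, with RT1-Ba (1.51-fold), RT1-Bb (1.44-fold), RT1-Da (1.41-fold) and the invariant chain Cd74 (1.39-fold) higher and Fscn1 lower. In the eosinophil and type 2 list 6 of 12 tested members rose and 2 fell (6 and 2 adjusted over the list alone). The type 2 response list had camera adjusted p = 5.71e-05 and adjusted p = 0.0311 with an estimated correlation. The chitinase Chia rose 3.62-fold, Retnla 6.25-fold and Arg1 1.77-fold, genes also expressed by epithelium and macrophages, whereas the lipoxygenase Alox15 fell 2.35-fold and the eosinophil attractant Ccl24 fell 2.1-fold. The Il1rl1 call was lost without air replicates 1, 2, 3 and 6 or CNC replicates 1, 2 and 6 in turn (adjusted p from 0.0544 to 0.0982). The Il1rl1 call also ended with each of upper-quartile scaling, library size alone, no count filter, limma-voom, 1 surrogate variable, the clock covariate and CNC replicates 3 and 6 left out (adjusted p from 0.0507 to 0.263).

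**Figure D2:**
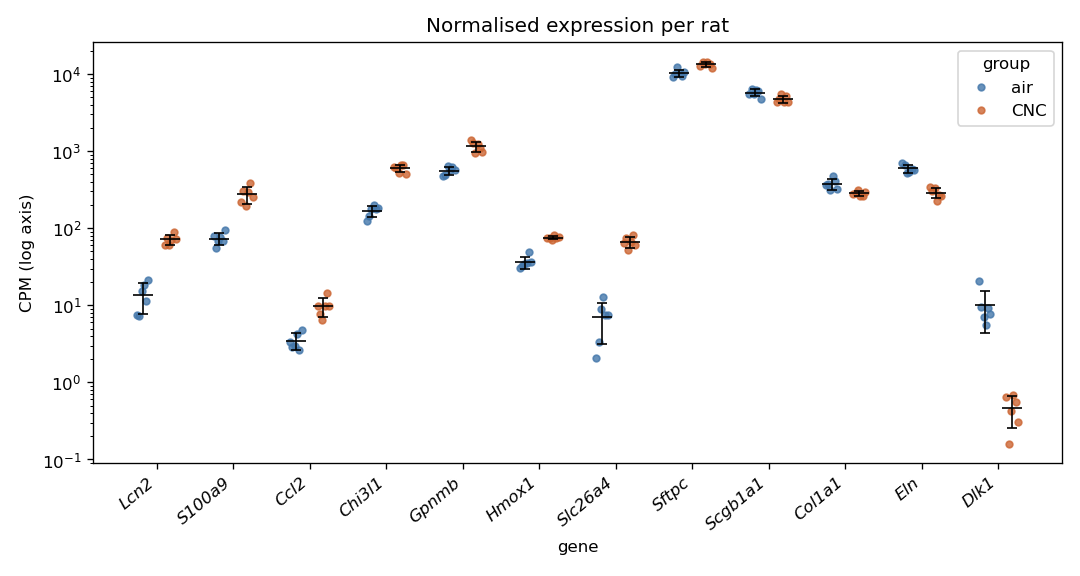
CPM on a log axis of 12 genes in each rat, air in blue and CNC in orange, with the mean and SD of each group (n = 6) as black bars. Mean Lcn2 rose from 13.4 to 71.4 CPM and mean Eln fell from 596 to 289.9 CPM.

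Most endothelial and matrix genes fell by small amounts. In the endothelial list 26 of 30 tested members fell and 0 rose (28 and 0 adjusted over the list alone), with a median of -0.29. The endothelial list had camera adjusted p = 1.35e-16, exact permutation p = 0.00216 and adjusted p = 0.0625 with an estimated correlation. Its called members included the junction protein Cdh5 (1.29-fold), the receptors Aplnr (1.35-fold) and Calcrl (1.29-fold) and Ednrb (1.22-fold). In the fibroblast and matrix list 25 of 44 tested members fell and 4 rose (32 and 4 adjusted over the list alone), with a median of -0.27. The matrix list had camera adjusted p = 3.3e-12 and adjusted p = 0.0424 with an estimated correlation. Basement membrane collagens Col4a1 (1.32-fold) and Col4a2 (1.33-fold) fell, as did Col5a2 (1.26-fold) and Col1a1 (1.33-fold), while Timp1 (1.2-fold), Cthrc1 and Mmp14 rose. The Timp1 call was lost without air replicates 4 and 5 together (adjusted p = 0.0822). Among smooth muscle markers 8 of 15 tested members fell and 0 rose (9 and 0 adjusted over the list alone). The smooth muscle list had camera adjusted p = 4.63e-05, exact permutation p = 0.013 and adjusted p = 0.244 with an estimated correlation, with Pdgfrb (1.36-fold) and Notch3 (1.36-fold) lower. For red cell markers 7 of 9 tested members fell and 0 rose (7 and 0 adjusted over the list alone). The red cell list had camera adjusted p = 4.34e-06, exact permutation p = 0.00216 and adjusted p = 0.0625 with an estimated correlation. The sum of these markers was 2882 ± 261 CPM in air and 2032 ± 226 CPM in CNC (SD, n = 6 per group). Heart muscle markers summed to 223 ± 187 CPM in air and 109 ± 53.8 CPM in CNC (SD, n = 6 per group, exact permutation p = 0.221). In that list 1 of 16 tested members fell and 0 rose (0 and 0 adjusted over the list alone), the member that fell being Kcnj3. The Kcnj3 call was lost without air replicates 3, 4 and 6 or CNC replicates 1 and 4 in turn (adjusted p from 0.0631 to 0.0726). The Kcnj3 call also ended with each of no count filter, the DESeq2 Wald test, the heart muscle covariate, the clock covariate and air replicates 4 and 5 left out (adjusted p from 0.0547 to 0.388). The list's camera call (adjusted p = 0.0235) was lost with an estimated correlation (adjusted p = 0.713) and without air replicate 4 (adjusted p = 0.151) or without air replicate 5 (adjusted p = 0.0859) or without CNC replicate 4 (adjusted p = 0.0909), and over all alternatives its adjusted p ran from 1.43e-10 to 0.775. Adipocyte markers were called lower (camera adjusted p = 0.0438, adjusted p = 0.248 with an estimated correlation), where 3 of 8 tested members fell and 1 rose (5 and 1 adjusted over the list alone). Cidea rose, and Lipe, Fabp4 and Tusc5 fell. The list's call was lost without air replicate 4 (adjusted p = 0.0566) or without CNC replicate 3 (adjusted p = 0.0722) or without CNC replicate 6 (adjusted p = 0.0747), and over all alternatives its adjusted p ran from 0.00223 to 0.248. The Fabp4 call was lost without air replicates 1, 4 and 6 or CNC replicates 1, 3, 5 and 6 in turn (adjusted p from 0.0519 to 0.0745). The Tusc5 call was lost without air replicate 1 (adjusted p = 0.0533). The Tusc5 call also ended with each of the clock covariate, air replicates 4 and 5 left out and CNC replicates 3 and 6 left out (adjusted p from 0.0528 to 0.0789).

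Most alveolar type 2 cell genes rose and most type 1 cell genes fell. In the type 2 and surfactant list 16 of 21 tested members rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.35. The alveolar type 2 list had camera adjusted p = 1.31e-15, exact permutation p = 0.00216 and adjusted p = 0.10 with an estimated correlation. Surfactant protein Sftpc rose 1.31-fold, the mucin Muc1 1.68-fold, the cathepsin Ctsh 1.51-fold and the surfactant lipid enzyme Lpcat1 1.34-fold. In the type 1 list 11 of 21 tested members fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.16. The alveolar type 1 list had camera adjusted p = 2.66e-05, exact permutation p = 0.0238 and adjusted p = 0.368 with an estimated correlation. Among its called members were Cav1 (1.29-fold), Cav2 (1.22-fold), Clic5 (1.16-fold) and Vegfa (1.19-fold), and the direction of the list turned with the clock covariate (adjusted p = 0.645). Under it the calls of these genes ended too, at log2 fold changes of -0.19, -0.17, -0.08 and -0.14, against -0.37, -0.29, -0.22 and -0.26 (adjusted p from 0.176 to 0.614). The cell source of these genes was not resolved in a piece of lung, and the endothelial list fell too, with a median of -0.29. Club and secretory cell genes moved both ways and the list was not called (camera adjusted p = 0.232), where 7 of 25 tested members rose and 6 fell (7 and 6 adjusted over the list alone). It passed without air replicate 4 (adjusted p = 0.0402), and over all alternatives its adjusted p ran from 0.00264 to 0.73. The club cell secretoglobin Scgb1a1 fell 1.21-fold, a call lost without air replicates 4 and 5 together (adjusted p = 0.0684) and with the clock covariate (adjusted p = 0.284), and the monooxygenase Cyp4b1 1.55-fold. Bpifa1 fell 11.1-fold, a value that rests on air replicate 4, without which the log2 fold change was -1.52, and the Bpifa1 call was lost without air replicate 4 or CNC replicates 1, 2 and 4 in turn (adjusted p from 0.0503 to 0.128). The Bpifa1 call also ended with each of limma-voom, limma-voom with quality weights, robust edgeR, the heart muscle covariate, air replicates 4 and 5 left out and CNC replicates 3 and 6 left out (adjusted p from 0.075 to 0.495). The goblet cell mucin Muc5ac was below the count filter, with 4 counts in air and 14 in CNC. In the epithelial damage list 4 of 17 tested members rose and 4 fell (4 and 6 adjusted over the list alone). Camera did not call it (adjusted p = 0.361), but its mean per rat was higher by 0.27 log2 CPM (exact permutation p = 0.00216). Lcn2, Lgals3, Plaur (1.57-fold) and Ereg (2.51-fold) rose, and Krt19, Hbegf, Cdkn1a and Itgb6 fell. Ciliated cell genes were not called (camera adjusted p = 0.835), where 2 of 35 tested members rose and 2 fell (1 and 1 adjusted over the list alone), namely Cfap44 and Tubb4b higher and Tppp3 and Fam183b lower. The Cfap44 call was lost without air replicates 1, 2, 3 and 6 or CNC replicates 1, 2 and 5 in turn (adjusted p from 0.0637 to 0.10). The Cfap44 call also ended with each of upper-quartile scaling, library size alone, robust edgeR, 1 surrogate variable and the clock covariate (adjusted p from 0.0501 to 0.431). The Fam183b call was lost without air replicates 2, 4 and 5 or CNC replicates 1, 2, 4 and 6 in turn (adjusted p from 0.0511 to 0.0818). The Fam183b call also ended with each of the heart muscle covariate, the clock covariate, air replicates 4 and 5 left out and CNC replicates 3 and 6 left out (adjusted p from 0.0552 to 0.60). The Tubb4b call ended with each of the clock covariate and CNC replicates 3 and 6 left out (adjusted p from 0.0521 to 0.598). The ciliated list was called lower with the clock covariate (adjusted p = 0.0362).

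**Figure D3:**
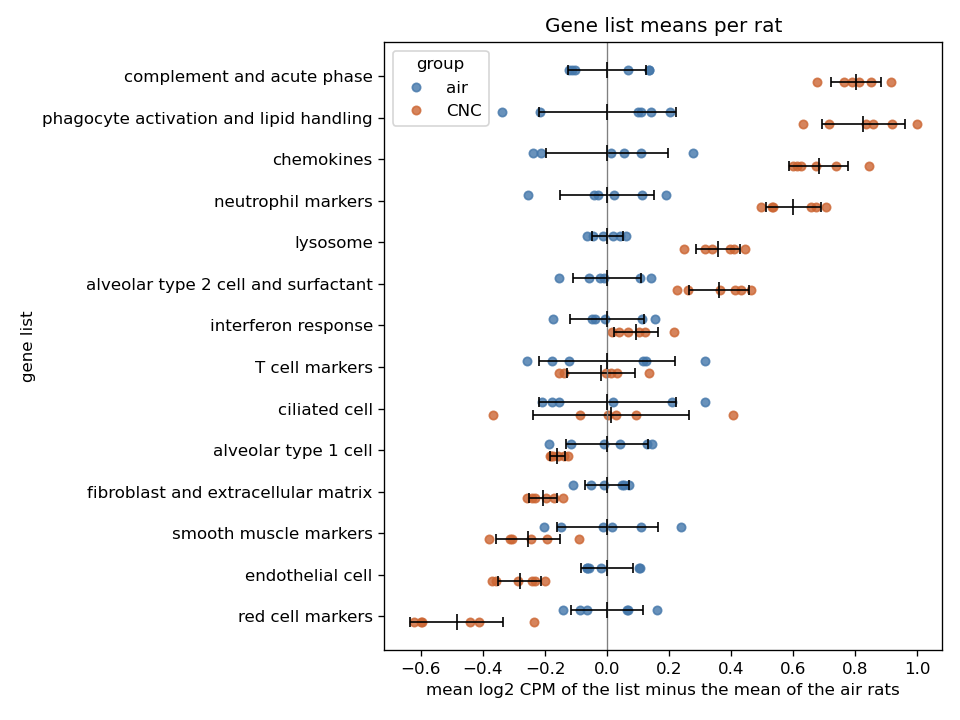
Mean log2 CPM over the tested members of 14 gene lists in each rat, shown relative to the mean of the air rats, air in blue and CNC in orange, with the mean and SD of each group (n = 6) in black. The complement and acute phase mean of CNC rats lay 0.80 above air and the endothelial mean lay -0.28 from it.

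Most unfolded protein and cholesterol synthesis genes rose, as did part of the Nrf2 list. In the Nrf2 and oxidative stress list 17 of 36 tested members rose and 2 fell (22 and 4 adjusted over the list alone). The Nrf2 list had camera adjusted p = 8.36e-09, exact permutation p = 0.00216 and adjusted p = 0.17 with an estimated correlation. The mitochondrial superoxide dismutase Sod2 rose 2.42-fold, heme oxygenase Hmox1 2.1-fold, the cystine transporter Slc7a11 3.73-fold and Prdx1 1.3-fold, while Gpx3 and Sod3 fell. In CNC replicates 3 and 6 the mean of the list was 6.40 and 6.44 log2 CPM, against 6.01 to 6.07 in the other 4 CNC rats and 5.70 to 5.87 in air. Without these libraries, left out after their values were seen, the list oxidative stress and Nrf2 targets kept its call (camera adjusted p = 6.11e-05). Nqo1, a classical Nrf2 target, had 49.99 ± 3.34 CPM in air and 68.8 ± 30.1 CPM in CNC and did not pass the test (SD, n = 6 per group, adjusted p = 0.13 by edgeR). Its level was 102 and 112 CPM in CNC replicates 3 and 6, and 47.3 to 54.2 CPM in the other 4 CNC rats. Without these libraries the log2 fold change of the gene Nqo1 was -0.02 (adjusted p = 0.836). In the unfolded protein list 21 of 30 tested members rose and 0 fell (22 and 0 adjusted over the list alone). The unfolded protein list had camera adjusted p = 5.74e-10 and adjusted p = 0.0311 with an estimated correlation. Its called members included Sdf2l1 (1.92-fold), Calr (1.24-fold) and Pdia6 (1.23-fold). Among cholesterol synthesis genes 17 of 24 tested members rose and 0 fell (20 and 0 adjusted over the list alone). The cholesterol synthesis list had camera adjusted p = 3.7e-08 and adjusted p = 0.166 with an estimated correlation. Called members were, among others, Fdps (1.42-fold), Mvd (1.62-fold) and Cyp51 (1.4-fold). For fatty acid synthesis 11 of 22 tested members rose and 0 fell (13 and 0 adjusted over the list alone). The fatty acid list had camera adjusted p = 9.8e-07 and adjusted p = 0.0637 with an estimated correlation. Its called members included Dgat2 (1.78-fold) and Fasn (1.61-fold). Of cell cycle genes 22 of 48 tested members rose and 0 fell (28 and 0 adjusted over the list alone). The cell cycle list had camera adjusted p = 1.27e-07, exact permutation p = 0.00433 and adjusted p = 0.256 with an estimated correlation. Among its called members were Mcm5 (1.99-fold), Ect2 (1.92-fold), Tk1 (1.58-fold) and the proliferation marker Mki67 (1.35-fold). Of ribosomal protein genes 27 of 54 tested members rose and 0 fell (35 and 0 adjusted over the list alone), with a median of 0.13. Their camera adjusted p was 2.37e-09, and adjusted p = 0.28 with an estimated correlation. Of oxidative phosphorylation genes 20 of 44 tested members rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 0.11. Their camera adjusted p was 1.68e-05, and adjusted p = 0.368 with an estimated correlation. The call of oxidative phosphorylation genes was also lost with the clock covariate (adjusted p = 0.0583). In the xenobiotic list 6 of 18 tested members fell and 0 rose (6 and 0 adjusted over the list alone). The xenobiotic list had camera adjusted p = 0.000342 and adjusted p = 0.0311 with an estimated correlation, with the monooxygenases Fmo2 (1.84-fold) and Fmo1 (1.3-fold) lower.

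Lymphocyte and mast cell lists were not called by camera. T cell markers had 0 higher and 2 lower of 24 tested members (0 and 1 adjusted over the list alone, camera adjusted p = 0.468, exact permutation p = 0.842). NK cell markers had 1 higher and 2 lower of 17 tested members (1 and 2 adjusted over the list alone, camera adjusted p = 0.156, exact permutation p = 0.374). B and plasma cell markers had 4 higher and 2 lower of 20 tested members (4 and 2 adjusted over the list alone, camera adjusted p = 0.576, exact permutation p = 0.416). Mast cell markers had 2 higher and 2 lower of 6 tested members (2 and 2 adjusted over the list alone, camera adjusted p = 0.665, exact permutation p = 0.825). In the B and plasma cell list Irf4 (1.66-fold), Fcrla (1.55-fold), Derl3 and Sdc1 rose, and Prdm1 and Bank1 fell. Of T and NK cell genes Cst7 rose and Gzmk, Prf1, Cd8a and Tcf7 fell. In the mast cell list Hdc and Il1rl1 rose, and Kit and Gata2 fell. The cells that expressed these list members were not resolved in a piece of lung. The Cd8a call was lost without air replicates 1, 3, 4 and 5 or CNC replicates 1, 2, 4, 5 and 6 in turn (adjusted p from 0.0573 to 0.0967). The Cd8a call also ended with each of no count filter, the heart muscle covariate, the clock covariate and air replicates 4 and 5 left out (adjusted p from 0.059 to 0.179). The Gzmk call was lost without air replicates 1, 4 and 6 or CNC replicates 1, 2, 4 and 5 in turn (adjusted p from 0.0538 to 0.0793). The Gzmk call also ended with each of the heart muscle covariate and air replicates 4 and 5 left out (adjusted p from 0.0668 to 0.104). The Prf1 call ended with each of the clock covariate and air replicates 4 and 5 left out (adjusted p from 0.0651 to 0.0658). The Tcf7 call ended with air replicates 4 and 5 left out (adjusted p = 0.0517). The Sdc1 call ended with air replicates 4 and 5 left out (adjusted p = 0.062). The Il1rl1 call was lost without air replicates 1, 2, 3 and 6 or CNC replicates 1, 2 and 6 in turn (adjusted p from 0.0544 to 0.0982). The NK cell list passed without CNC replicate 3 (adjusted p = 0.0201). Over all alternatives the NK list's adjusted p ran from 5.33e-05 to 0.726. With the clock covariate the T cell list (adjusted p = 5.1e-09) and the NK cell list (adjusted p = 5.33e-05) were called lower. The B cell list had the opposite direction with it (adjusted p = 0.00634). These p values are from camera at the preset correlation of 0.01. Without the covariate the estimated correlation was 0.51 for the T cell list and 0.46 for the NK cell list. A test with an estimated correlation was not run with the covariate, so these calls may be too strong.

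Interferon, inflammasome and hormone response lists were not called by camera either. Interferon response genes had 8 higher and 0 lower of 40 tested members (8 and 0 adjusted over the list alone, camera adjusted p = 0.0662, exact permutation p = 0.123). Inflammasome genes had 6 higher and 2 lower of 14 tested members (7 and 2 adjusted over the list alone, camera adjusted p = 0.0985, exact permutation p = 0.00649). Glucocorticoid targets had 5 higher and 3 lower of 23 tested members (5 and 4 adjusted over the list alone, camera adjusted p = 0.108, exact permutation p = 0.0173). Immediate early genes had 8 higher and 1 lower of 34 tested members (8 and 2 adjusted over the list alone, camera adjusted p = 0.285, exact permutation p = 0.0736). Endothelial adhesion genes had 2 higher and 6 lower of 15 tested members (2 and 7 adjusted over the list alone, camera adjusted p = 0.296, exact permutation p = 0.554). The interferon list passed without air replicate 4 (adjusted p = 0.00393) or without air replicate 6 (adjusted p = 0.0153) or without CNC replicate 1 (adjusted p = 0.0208) or without CNC replicate 2 (adjusted p = 0.039). With the clock covariate it had the opposite direction (adjusted p = 0.0203), and over all alternatives its adjusted p ran from 0.00393 to 0.73. The glucocorticoid list passed without air replicate 1 (adjusted p = 0.0484), and over all alternatives its adjusted p ran from 0.0284 to 0.851. Of glucocorticoid targets Nfkbia, Mt1a, Mt2A, Lcn2 and Cebpb rose and Zbtb16, Cdkn1a and Pik3r1 fell. The Zbtb16 call was lost without air replicates 3, 4 and 5 or CNC replicates 1, 2, 3, 4, 5 and 6 in turn (adjusted p from 0.0505 to 0.146). The Zbtb16 call also ended with each of the DESeq2 Wald test, limma-voom, limma-voom with quality weights, robust edgeR, 1 surrogate variable, the heart muscle covariate, air replicates 4 and 5 left out and CNC replicates 3 and 6 left out (adjusted p from 0.0582 to 0.359). Txnip and P2rx7 fell among inflammasome genes. Nr4a3 (2.82-fold) and Myc (1.31-fold) rose among immediate early genes, and Dusp6 fell. Sele rose among adhesion genes.

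Lists of DNA damage, heat shock and neighbouring tissues were not called by camera. DNA damage response genes had 4 higher and 2 lower of 23 tested members (4 and 2 adjusted over the list alone, camera adjusted p = 0.853, exact permutation p = 0.305). Heat shock genes had 2 higher and 2 lower of 21 tested members (1 and 1 adjusted over the list alone, camera adjusted p = 0.677, exact permutation p = 0.959). Skeletal muscle markers had 0 higher and 1 lower of 7 tested members (0 and 1 adjusted over the list alone, camera adjusted p = 0.361, exact permutation p = 0.24). Mesothelial markers had 0 higher and 1 lower of 9 tested members (0 and 1 adjusted over the list alone, camera adjusted p = 0.665, exact permutation p = 0.97). Lymph node and thymus markers had 0 higher and 1 lower of 7 tested members (0 and 0 adjusted over the list alone, camera adjusted p = 0.853, exact permutation p = 0.613). Ccng1, Aen and Gdf15 rose among DNA damage response genes, and Cdkn1a and Sesn1 fell. Hspe1 and Hspd1 rose and Hspb1 and Cryab fell among heat shock genes. The Gdf15 call ended with each of the clock covariate and CNC replicates 3 and 6 left out (adjusted p from 0.0594 to 0.57). The Hspd1 call was lost without air replicates 1, 2 and 3 or CNC replicates 1, 2 and 5 in turn (adjusted p from 0.0681 to 0.0981). The Hspd1 call also ended with each of upper-quartile scaling, library size alone and the clock covariate (adjusted p from 0.0675 to 0.388). The Hspe1 call ended with each of the clock covariate, air replicates 4 and 5 left out and CNC replicates 3 and 6 left out (adjusted p from 0.0627 to 0.529). The Hspb1 call was lost without air replicates 3, 5 and 6 or CNC replicates 1 and 5 in turn (adjusted p from 0.0634 to 0.0832). The Hspb1 call also ended with each of the heart muscle covariate, the clock covariate and air replicates 4 and 5 left out (adjusted p from 0.0585 to 0.292). The Sesn1 call was lost without air replicates 1, 2, 4 and 6 or CNC replicates 1, 3 and 5 in turn (adjusted p from 0.0566 to 0.103). The Sesn1 call also ended with each of no count filter, the clock covariate and CNC replicates 3 and 6 left out (adjusted p from 0.0631 to 0.195). Other falls were Pygm in the skeletal muscle list, Krt19 in the mesothelial list and Ccl21 in the lymph node list. The Pygm call was lost without air replicate 5 or CNC replicates 4 and 5 in turn (adjusted p from 0.0502 to 0.0517). The Pygm call also ended with air replicates 4 and 5 left out (adjusted p = 0.116). The Ccl21 call was lost without air replicates 3, 4, 5 and 6 or CNC replicates 1, 2, 3, 4 and 6 in turn (adjusted p from 0.0568 to 0.105). With the clock covariate the mesothelial list had the opposite direction (adjusted p = 0.000266). Under it the skeletal muscle (adjusted p = 0.00149) and lymph node (adjusted p = 0.0101) lists were called lower. In 8 lists the median, the mean or the mean per rat differed in sign from the camera test. These were the club, endothelial adhesion, epithelial damage, mesothelial, mast cell, heat shock, ciliated and lymph node lists. Lists of neuroendocrine, cartilage and mitochondrially encoded genes had fewer than 3 tested members and were not tested.

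Clock genes differed between the groups, although the list as a whole was not called by camera (adjusted p = 0.0761, exact permutation p = 0.00433), where 8 of 18 tested members rose and 6 fell (8 and 6 adjusted over the list alone). It passed without air replicate 4 (adjusted p = 0.00334) or without CNC replicate 1 (adjusted p = 0.0481), and over all alternatives its adjusted p ran from 0.000384 to 0.851. Arntl, the positive arm of the clock, fell 1.94-fold and its partner Npas2 fell 1.73-fold, while Bhlhe41 rose 1.97-fold and Bhlhe40 1.5-fold. Bhlhe41 counts among the Dbp phase genes below and is also in the alveolar macrophage list, so its rise cannot be assigned to the clock alone. The mean of the 11 genes of the Dbp phase minus that of the 5 genes of the Arntl phase was 0.17 ± 0.45 log2 CPM in air and 1.43 ± 0.32 in CNC (SD, n = 6 per group, exact permutation p = 0.00433), with air replicate 4 at 1.01, inside the CNC range. The index and its genes were chosen after the values were seen. With the index as a covariate, the calls of Il1b (log2 fold change from 0.46 to 0.13), Il33 (log2 fold change from -0.30 to -0.12), Nfkbia (log2 fold change from 0.33 to 0.09), Fcrla (log2 fold change from 0.63 to 0.26), Clic5 (log2 fold change from -0.22 to -0.08) and Krt19 (log2 fold change from -0.20 to -0.02) ended, with less than 50% of the fold left. Arntl and Npas2, which are part of the index, also lost their calls and kept less than 50%. Of other genes named as higher, the covariate ended the calls of Ccl2 (0.0518), Cxcl1 (0.059), S100a8 (0.189), Sftpc (0.0954), Mki67 (0.151), Ccl3 (0.0516), Il1rn (0.155), Il1a (0.115), Itgam (0.10), Hdc (0.158), Cst7 (0.432) and Irf4 (0.328) (adjusted p in brackets). It also ended those of Derl3 (0.11), Plaur (0.164), Ereg (0.0576), Slc7a11 (0.0527), Prdx1 (0.126), Mvd (0.202), Mcm5 (0.0633), Tk1 (0.105), Ccng1 (0.0678), Myc (0.0694), Bhlhe40 (0.0504), Mt1a (0.333) and Mt2A (0.402). Of other genes named as lower, it ended the calls of Gata2 (0.0934), Kit (0.0585), P2rx7 (0.139), Calcrl (0.0568) and Lipe (0.169). A call could end without a smaller fold. Over all changed genes the fold was a median of 0.955 of that without the covariate, and the standard error rose by a median factor of 2.01.

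Among the remaining genes of largest change, some were uncertain. Col1a2-2 carries a copy suffix, and its 15.7-fold rise came from 3 of 6 CNC rats above all air rats (from 1.1 ± 0.376 to 17.4 ± 23.3 CPM, SD, n = 6 per group). These were CNC replicates 2, 4 and 5, at 60.2, 25.6 and 16.4 CPM, so the size of the rise rests on these 3 rats, most of all on replicate 2. The call was kept on leaving out each library (adjusted p at most 0.0226 by edgeR). Naa11 fell 3.68-fold with 1 of 6 CNC rats below all air rats, and Zbtb16, a glucocorticoid target, fell 2.39-fold with 3 of 6. Without air replicate 4 the log2 fold change of Zbtb16 was -0.75, against -1.26. The Naa11 call was lost without air replicate 1 or CNC replicates 2 and 3 in turn (adjusted p from 0.0523 to 0.076). The Naa11 call also ended with each of limma-voom, limma-voom with quality weights and the clock covariate (adjusted p from 0.0741 to 0.146). The Zbtb16 call was lost without air replicates 3, 4 and 5 or CNC replicates 1, 2, 3, 4, 5 and 6 in turn (adjusted p from 0.0505 to 0.146). The Col1a2-2 call ended with each of limma-voom, limma-voom with quality weights and the clock covariate (adjusted p from 0.272 to 0.563). With limma-voom the adjusted p of Zbtb16 was 0.225. Rpl10l, a copy of a ribosomal protein gene, fell 3.11-fold and is uncertain for shared reads, and the Rpl10l call was lost without air replicate 2 (adjusted p = 0.0595). The size of the Rpl10l fall depends on CNC replicate 6. It had 2.42 CPM, inside the range of the air rats, against 0.0687 to 0.868 CPM in the other CNC rats. The Rpl10l call also ended with the clock covariate (adjusted p = 0.212). The potassium channel subunit Kcnmb2 fell 3.17-fold, the natriuretic peptide clearance receptor Npr3 2.41-fold, Spon2 2.07-fold and Mlc1 2.25-fold. With the clock covariate the log2 fold change of Npr3 went from -1.27 to -0.24 (adjusted p = 0.673) and that of Mlc1 from -1.17 to -0.72 (adjusted p = 0.318), and both calls ended. So did those of Col1a2-2, Mab21l3, Naa11, Rpl10l and Ccl24 among the 24 largest changes (adjusted p from 0.0915 to 0.563). Members of lists named because their count was 5 or fewer were chosen after their values were seen.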

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

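The tests of collection time, of dilution, of imprinted genes and of other splits by the permutation test of lists were chosen only after the result was seen, as were the test of 1 shared dilution factor, the breakdown of the calls that ended and the use of the clock and heart muscle covariates.

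A library stood apart from the other 5 of its group in 21 of 458 groups of values, about the 1 in 20 that chance gives, with 6 of the 21 in air replicate 4 and 5 in CNC replicate 3. The value given is the gap to the nearest library as a share of the group's range. Among air libraries, Prf1 (0.848), Lgals3bp (0.737) and RT1-Da (0.647) were highest and Arntl (0.782), Card9 (0.664) and Gpam (0.641) lowest in replicate 4. Hmox1 (0.626) was highest and Ereg (0.695) lowest in air replicate 5, Il1b (0.680) was lowest in replicate 2, Ccl24 (0.670) in replicate 3 and Fdps (0.700) in replicate 1, where the immediate early list (0.667) was highest. Among CNC libraries, the inflammasome (0.768), endothelial adhesion (0.692) and cytokine (0.689) lists, Clic5 (0.633) and Mt1a (0.628) were lowest in replicate 3. Rps25 (0.664) was lowest and Hspe1 (0.650) highest in CNC replicate 6, Il18 (0.628) was lowest in replicate 5 and Lipa (0.638) was highest in replicate 1.

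Other splits of the 12 libraries were drawn, 100 with the real one. For the number of changed genes, 1 of the 100 gave a result as large, namely the real one (3691 in the real split, at most 700 in the others). For the lists by camera, 8 of 100 gave as many, so that chance cannot be excluded for that number (28 in the real split, at most 33 in the others). The other splits that gave at least 28 had 1, 4 or 5 CNC libraries in the part named air. They thus kept some of the contrast between CNC and air. Splits with 3 CNC libraries in that part gave 6 to 23 lists. For the lists by the permutation test, 1 of 100 gave as many, again the real one (30 in the real split, at most 8 in the others). The results for genes and for the permutation test argue against chance in how single rats were grouped. They cannot exclude a difference between cages or chambers, since the splits treat rats as independent and cages were not analysed.

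The complement, phagocyte, chemokine and neutrophil lists rose while clock genes differed between the groups. With the clock index as a covariate the fold of their 65 called members was a median of 0.935 of that without it, from 0.854 to 1.05 on leaving out each library. The index had a correlation of 0.871 with the group, so its slope rests on differences between rats of the same group. The small change of the fold shows only that these genes followed the index little within the groups. It cannot decide on the clock difference as the whole cause. The median log2 fold change of the 65 was 0.85 before and 0.86 after, and 29 of the 65 still passed. In the other 36 the median log2 fold change was 0.61 before and 0.51 after and the median standard error 0.12 and 0.24, and 26 of the 36 would have missed with their former fold as well while 10 would have passed. The clock difference itself, 1.26 on the log2 scale with the phases moving in opposite directions, is consistent with lungs collected at different times of day, but an effect of the exposure on the clock stays open, as do single genes, since 626 of the 3691 changed genes (16.96%) kept less than 50% of their fold.

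The endothelial, matrix, alveolar type 1 and smooth muscle lists fell together, by -0.23 in the mean per rat (exact permutation p = 0.00216). A heart muscle covariate left a median of 1.03 of the fold of their 69 called members, with 66 still passing. Scaling moved the median of all genes by at most 0.0229 in size. The fall was thus not removed by this covariate, whose slope rests on differences within groups, or by the choice among these scalings. The scalings were compared only with each other, so a shift common to them would not show. The spread of the 109 members' folds was 5.19 per degree of freedom against at most 3.61 in the other splits (exact permutation p = 0.00216). This cannot decide on a single shared dilution factor as the whole cause. The other splits mix CNC and air rats within each part, which widens the variance there and lowers their spread (median 0.678). Dilution by added leukocytes as the whole or a part of the fall stays open. Ciliated and mesothelial genes moved by 0.0204, a difference of 0.247 from the structural lists (exact permutation p = 0.325) that decides nothing. The alveolar type 2 list, also of resident cells, rose by 0.36 (exact permutation p = 0.00216), so resident lists did not all fall. A lower expression per cell stays open too. With the clock covariate the 69 called members of the falling lists kept a median of 0.997 of their fold (0.814 to 1.21 on leaving out each library). Of these, 92.8% had the same sign and 22 still passed, although the type 1 list turned in direction (adjusted p = 0.645).

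Dlk1 and Meg3, neighbours in 1 imprinted cluster, were both lower after CNC. Meg3, listed under the symbol RGD1566401 and chosen after its values were seen, fell 10.2-fold, from 5.15 ± 3.18 to 0.491 ± 0.183 CPM (SD, n = 6 per group, adjusted p = 2.29e-05 by edgeR), lower in 6 of 6 CNC rats than in any air rat. A fall of imprinted genes as a group may be part of it, but 24 others gave a camera p of 0.102, with 7 lower, 2 higher and a median of -0.03, so that this stays undecided. Dlk1 was among the genes followed singly under the other settings, and Meg3 was not. No other technical explanation was tested for the pair as such.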

How the results depend on the processing

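The clock and heart muscle covariates and the fits without air replicates 4 and 5 and without CNC replicates 3 and 6 were chosen after seeing the data. No paired analysis was possible because the labels give no replicate number shared between groups and the numbers used here follow the order of the labels. Requiring a fold of at least 1.5 left 542 genes, 426 higher and 116 lower, since it asks for more than the test. With the clock covariate 922 genes passed, 585 higher and 337 lower, 664 of them shared with the 3691 and 0 in the opposite direction, and the standard error rose by a median factor of 2.01. Under it Oasl (-0.0452) and Ahr (0.0563) turned in log2 fold change, and the B cell (adjusted p = 0.00634), interferon (0.0203), alveolar type 1 (0.645) and mesothelial (0.000266) lists turned in direction. The T cell (5.10e-09), NK cell (5.33e-05), skeletal muscle (0.00149), lymph node (0.0101) and ciliated (0.0362) lists gained a call, and the cytokine (0.21) and oxidative phosphorylation (0.0583) lists lost theirs. These list results are from camera at the preset correlation alone. The cause was not tested. With an estimated correlation 9 lists passed, since that test widens the spread for members that move together. Leaving out each library gave 3091 to 3722 genes, 1712 to 1998 higher and 1379 to 1726 lower, 27 to 30 lists by camera, 29 to 31 by the permutation test and a library size p of 0.268 to 1. Other scalings, filters, tests and 1 surrogate variable gave 3406 to 4117 genes, the heart muscle covariate gave 3627, the fit without air replicates 4 and 5 gave 3592 and that without CNC replicates 3 and 6 gave 3508. These last fits ended the calls of 17 and 14 of 184 genes followed singly. With library size alone 43.9% of the changed genes were higher, and with upper-quartile scaling 47.8%. Depth may limit genes of low count, which was not tested. Tnf, below the filter, rose by 1.42 on the log2 scale without the filter (adjusted p = 0.0551) and passed the DESeq2 Wald test (0.0351). Il6 (0.515) and Muc5ac (0.167) did not pass without the filter and got no adjusted p from DESeq2.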

Other observations

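Gene families read from symbol stems, a grouping chosen after the results were seen, gave 21 called stems of 175 by camera, 14 higher and 7 lower. Of the solute carriers 72 of 244 tested members were higher and 18 lower, with a median log2 fold change of 0.06 (camera adjusted p = 0.00101, adjusted p = 0.0404 with an estimated correlation). Of the Adamts family of secreted proteases, 7 of 15 fell and 0 rose (camera adjusted p = 0.00140, adjusted p = 0.230 with an estimated correlation). Of the Sox transcription factors 5 of 11 fell and 0 rose (camera adjusted p = 0.00589, adjusted p = 0.257 with an estimated correlation). Of zinc finger genes with the stem Zfp 25 of 228 fell and 4 rose (camera adjusted p = 0.0228, adjusted p = 0.446 with an estimated correlation). Their median log2 fold change was -0.08. The share of Zfp genes that fell was near that of all tested genes (1710 of 15019), and only the rises were few (against 1981 of 15019). Immunoproteasome and proteasome beta subunits, Psmb, had 5 of 10 members higher and 0 lower (camera adjusted p = 0.0364, adjusted p = 0.722 with an estimated correlation).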
